A study of Mus musculus with 12 samples.

How the data were processed

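The series measured RNA in bone marrow cells of C57BL/6 mice whose libraries carry the genotype labels WT or KO, the KO label referring to U2af1, the gene for the small subunit of the splicing factor that recognises the 3' splice site. There were 12 libraries in 4 groups of 3: lineage-negative marrow cells (LinNeg) and LSK cells (the lineage-negative, Sca-1 and c-Kit positive fraction that holds the stem cells), each with WT and KO labels. Per the labels' protocols, cells were lineage-depleted on magnetic columns and flow-sorted, ribosomal RNA was depleted, and libraries were made from total RNA with a NEBNext Ultra II kit. The LSK table also carries the label BMT, which the labels do not spell out. The labels do not say that replicates came from separate animals, so the p-values per gene measure the spread between these libraries, which may be technical. The p-values of the list and overlap tests treat genes as the units and do not measure variation between replicates.

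Per the submitters' processing notes, the tools were HISAT2, SAMtools 1.10, StringTie and DESeq2, with the mouse build mm10. The counting program and annotation are not given in the sources used here. Rows named for reads without a feature, as htseq-count writes them, are in both tables. The values used are 2 tables of the authors' own comparisons, KO against WT within LinNeg and within LSK. Values per library were not used here, and the depth of each library is therefore unknown. Per the file headers, each gene has the authors' mean of normalized counts over the libraries of the comparison (a signal on a linear scale), the authors' log2 fold change with its standard error on the log2 scale, the authors' Wald statistic (a score), and the authors' p-value and adjusted p-value. The deposited statistic equalled the deposited log2 fold change over its standard error within rounding, so the fold changes were not shrunken, and log2 fold changes were recomputed as statistic times standard error because the deposited ones are rounded.

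Each table had 24542 rows. The 5 rows that name no gene and 4 rows with repeated symbols were left out, and 26 symbols had been turned into dates by a spreadsheet. Reads without a feature made up 38.0% of the LinNeg total and 26.4% of the LSK total. The ribosomal RNA precursor Rn45s held 13.3% of the summed gene means in LinNeg and 19.3% in LSK. Of the symbols, 97.0% were found in GENCODE M21, from which the coordinates come (build mm10). An adjusted p was present for 17108 genes in LinNeg and 16482 in LSK. A further 53 genes in LinNeg and 3 in LSK have a fold change and no p, as DESeq2, run by the authors, leaves them when single libraries stand far out.

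The tests had been planned on counts per library. Because the tables hold the authors' comparisons, the fallback fixed before the data were examined was used: a gene is called when the adjusted p of DESeq2, run by the authors, is under 0.05. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists with at least 5 tested members. An estimated correlation needs values per library and was not computed. There were 27 lists fixed before the data were examined. Of these 26 could be tested and 3 of their genes were found under older symbols. A further 11 lists, and 13 lists of transcripts of other organs and of neural cells, were written after the tables had been seen. The difference between the effects in LSK and LinNeg was tested per gene as the difference of the log2 fold changes over the root of the summed squared standard errors (two-sided normal test, Benjamini-Hochberg adjustment), and per list with cameraPR on that quotient. The tables were normalized separately, so levels are not compared across them. Overlap of calls was tested with Fisher's exact test, two-sided, beside the overlap of independent lists. Means per genotype label were derived from the mean and the fold change, taking 3 libraries on each side; for genes whose derived mean in a group is under 1 the fitted fold change is not a measured ratio. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

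Genes were named by a rule fixed before the data were examined: U2af1; the 10 largest rises and the 10 largest falls in each table among called genes with a mean of at least 100 and a proper gene name; up to 4 members with the smallest adjusted p from each called list and up to 2 from other lists; and the 5 largest differences of each sign with a mean of at least 100 in both tables. The rule also asked that all KO libraries lie beyond all WT libraries, which could not be applied. Genes with the 10 highest and lowest Wald statistics, and a few others said to be so, were added after their values were seen.

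Both tests were tested on simulated data. With the real standard errors of 15735 genes, the test of the difference called 80.0% of 100 genes with a simulated difference of 1 on the log2 scale, 98.0% of 100 genes with a difference of 2, and 7 of 15535 unchanged genes. The changed genes were drawn from those with a mean of at least 100 in both tables. The noise was normal with the same standard errors that the test used. The simulation therefore does not give the rate of calls among genes with lower means, or of false calls under other noise. With statistics shuffled over the genes, the list test called 0 of 520 unchanged lists and 59 of 60 shifted lists in each table. Shuffling removes the correlation between list members, so this checks the code and not the rate of false calls among correlated genes. Alternatives tried were no filter, a mean of at least 1e-06 of the summed means, a mean of at least 100, a fold change threshold, an FDR of 0.01, recentring on the median of all genes, ranks or log2 fold changes in the list test, a preset correlation of 0.05, and leaving out genes on X and Y or of other organs.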

Results

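RNA was sequenced from 12 libraries of mouse bone marrow, 3 for each combination of cell population (LinNeg or LSK) and U2af1 genotype label (WT or KO). The comparisons ask how gene expression differs between the KO and WT labels within each population, and whether the effect differs between the populations. All fold changes are of libraries labelled KO over libraries labelled WT, on the log2 scale unless a fold is named, and come from the authors' deposited tables. Depth per library is unknown and reads per library were not analysed here.

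U2af1 was higher, not lower, in the libraries labelled KO in both populations. In the authors' deposited table for LinNeg, U2af1 had a log2 fold change of 0.65 (standard error 0.19, adjusted p = 0.00293), and in the authors' deposited table for LSK it had one of 0.61 (standard error 0.06, adjusted p = 1.72e-25). The gene (ENSMUSG00000061613.13) lies on chromosome 17 from 31647081 to 31658892, minus strand, in mm10, and its main transcript has 8 exons. A count over the whole gene includes exons outside a deleted part, so it does not check the labels, and every direction here rests on the name the authors gave the comparison.

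In LinNeg cells, transcripts of monocytes, dendritic cells and neutrophils were far lower in libraries labelled KO, and transcripts of the erythroid lineage were higher. The authors' deposited table gave Mpeg1, a pore-forming protein of macrophages, a log2 fold change of -7.10 (standard error 0.14), Irf8, a transcription factor of the monocyte and dendritic lineage, -6.07 (standard error 0.15) and F13a1 -6.12 (standard error 0.15), with adjusted p listed as 0 for each. On the erythroid side the same authors' deposited table gave Klf1, a master regulator of red cell genes, 2.98 (standard error 0.24, adjusted p = 1.21e-32) and the anion exchanger Slc4a1 3.40 (standard error 0.28, adjusted p = 1.22e-31). In all, 7088 of 17108 genes were called, 3781 higher and 3307 lower, of which 2403 and 1640 changed by at least 2-fold.

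Of 38 monocyte, macrophage and dendritic cell genes, 25 fell and 1 rose (26 calls adjusted over the list alone, median -1.80, camera FDR 1.92e-42). Ly86 had a log2 fold change of -6.55 (standard error 0.28) in the authors' deposited table. Of 30 neutrophil granule genes 21 fell and 0 rose (23 calls adjusted over the list alone, median -2.51, camera FDR 5.98e-11). The authors' deposited table gave the granule enzymes Mpo -4.90 (standard error 0.25) and Prtn3 -3.73 (standard error 0.23). Lymphoid priming genes fell, with 12 of 20 lower and 2 higher (14 calls adjusted over the list alone, median -1.09, camera FDR 1.43e-07). The authors' deposited table gave the receptor Flt3 -6.51 (standard error 0.33). Megakaryocyte and platelet genes were lower in 16 and higher in 4 of 30 (22 calls adjusted over the list alone, median -1.04, camera FDR 0.00268). Itga2b, the platelet integrin, was at -2.20 (standard error 0.20) and Zfpm1 at 2.51 (standard error 0.23) in the authors' deposited table.

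Erythroid and heme synthesis genes rose in 38 of 40 and fell in 1 (39 calls adjusted over the list alone, median 2.19, camera FDR 1.66e-32). Ribosome biogenesis and MYC target genes rose in 39 of 41 (40 calls adjusted over the list alone, median 1.30, camera FDR 2.31e-15), led in the authors' deposited table by the polyamine enzyme Odc1 at 2.28 (standard error 0.23) and the nucleolar protein Gnl3 at 1.67 (standard error 0.21). Early spliceosome components rose in 20 of 44 and fell in 0 (24 calls adjusted over the list alone, median 0.43, camera FDR 0.0057), a call lost with a preset correlation of 0.05 (FDR 0.106) and with log2 fold changes, where the list stood at -0.03 relative to other genes (FDR 0.957). Prpf31 and Snrpa1 were each at 1.09 and Phf5a at 1.03 in the authors' deposited table. Transcripts of snoRNA host genes and others degraded by nonsense-mediated decay rose in 13 and fell in 1 of 26 (15 calls adjusted over the list alone, median 0.86, camera FDR 0.00676), such as Snhg3 at 1.76 (standard error 0.22) in the authors' deposited table.

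A further 7 lists passed the list test. DNA damage response genes rose in 25 and fell in 2 of 59 (28 calls adjusted over the list alone, median 0.32, camera FDR 0.0164). The authors' deposited table gave the end-joining protein Xrcc5 2.82 (standard error 0.20). Nuclear-encoded oxidative phosphorylation genes rose in 21 of 52 (18 calls adjusted over the list alone, median 0.28, camera FDR 0.0164). With log2 fold changes in the test, this list and the DNA damage list each stood at -0.12 relative to other genes (camera FDR 0.806 each). Genes of the BCL2 family, caspases and death receptors fell in 15 and rose in 2 of 42 (17 calls adjusted over the list alone, median -0.29, camera FDR 0.02). The authors' deposited table gave the TNF receptor Tnfrsf1a -2.28 (standard error 0.18). Cyclin-dependent kinase inhibitor and quiescence genes fell in 10 and rose in 2 of 21 (14 calls adjusted over the list alone, median -0.46, camera FDR 0.0173). Mast cell, basophil and eosinophil genes fell in 13 and rose in 5 of 26 (18 calls adjusted over the list alone, median -1.56, camera FDR 0.0164). Cpa3 was at -2.82 (standard error 0.22), while the mast cell proteases Cma1 and Tpsb2 were at 7.53 and 7.52 (standard errors 0.35 and 0.41) in the authors' deposited table. Endothelial and stromal genes fell in 7 and rose in 2 of 25 (9 calls adjusted over the list alone, median -0.24, camera FDR 0.0302). The authors' deposited table gave the chemokine Cxcl12 -4.11 (standard error 0.31). T, NK and innate lymphoid genes rose in 13 and fell in 2 of 30 (17 calls adjusted over the list alone, median 0.85, camera FDR 0.0249). The 24 members that are not thymus transcripts held 12 of these rises (median 0.85), and the 6 that are held 1.

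The lists that did not pass in LinNeg were stem and primitive progenitor genes (11 higher, 14 lower of 40, 26 calls adjusted over the list alone, camera FDR 0.0687, where the median of 0.35 and the test, downward, differ in sign) and p53 targets (9 higher, 8 lower of 38, 17 adjusted over the list alone). Further ones were cell cycle genes (20 higher, 11 lower of 61, 32 adjusted over the list alone), and splicing regulators (9 higher, 5 lower of 56, 13 adjusted over the list alone). Interferon-stimulated genes (9 higher, 11 lower of 47, 23 adjusted over the list alone, where the median of 0.21 and the test, downward, differ in sign), inflammatory cytokine and NF-kB genes (6 higher, 12 lower of 32, 18 adjusted over the list alone) and immediate early genes (4 higher, 1 lower of 22, 3 adjusted over the list alone) did not pass either. The same holds for stress response genes (12 higher, 11 lower of 34, 26 adjusted over the list alone), B cell genes (4 higher, 8 lower of 25, 12 adjusted over the list alone), cytosolic ribosomal proteins (7 higher, 0 lower of 76, 2 adjusted over the list alone) and replication-dependent histones (3 higher, 11 lower of 48, 5 adjusted over the list alone). The camera FDR of these lists ran from 0.0687 to 0.716. Of the mitochondrially encoded genes, 0 of 15 had a test in either table.

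Among genes with a mean of at least 100, the largest falls in the authors' deposited table were in Siglech (-11.21), Cd300c (-10.27), Tlr9 (-9.80), Kcng1 (-8.28), Cd209a (-8.11), Mefv (-7.96), Lmo1 (-7.39), Mpeg1, Kcnk12 (-7.10) and Tifab (-6.93); Siglech and Tlr9 are receptors of plasmacytoid dendritic cells. The largest rises under the same limit in the authors' deposited table were in Tcf23 (11.15), Mcpt4 (11.13), Glb1l3 (10.37), C2cd4a (10.33), Cldn8 (10.12), Xist (10.02), Elf5 (9.98), Spinkl (9.93), Svs3b (9.49) and Svs4 (9.47). For Tcf23, Mcpt4, Glb1l3, C2cd4a, Cldn8, Elf5, Siglech, Cd300c and Tlr9 the derived mean under a label was below 1, so their fitted folds are not measured ratios. Spinkl, Svs3b and Svs4 are transcripts of the seminal vesicle, and Xist, the RNA of the inactive X chromosome, had a standard error of 1.81 in the authors' deposited table, as Svs4 had one of 1.69. Those of Glb1l3, Cldn8 and Elf5 were wider, at 2.82, 2.81 and 2.34 in the authors' deposited table. The surface sialomucin Podxl was at 7.59 (standard error 0.30) and erythroferrone, Erfe, at 5.42 (standard error 0.30) in the authors' deposited table; both were named after their Wald statistics were seen. The median gene stood at 0.16, and recentring on it gave 3025 genes higher and 4116 lower and ended the list calls for DNA damage and oxidative phosphorylation (FDR 0.0501 each) and endothelial genes (FDR 0.0656). With a preset correlation of 0.05, 5 of the 15 list calls held, namely erythroid, monocyte and dendritic, neutrophil, lymphoid priming and ribosome biogenesis, the last of which was lost with log2 fold changes in the test (FDR 0.0871).

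In LSK cells, stem cell transcripts were lower in libraries labelled KO, and erythroid, neutrophil granule, ribosomal protein and nuclear-encoded oxidative phosphorylation transcripts were higher. The stem cell transcription factor Hlf had a log2 fold change of -3.95 (standard error 0.10) in the authors' deposited table, with adjusted p listed as 0. The transferrin receptor Tfrc was at 2.85 (standard error 0.10, adjusted p = 1.33e-194) and neutrophil elastase, Elane, at 2.52 (standard error 0.09, adjusted p = 6.62e-172) in the authors' deposited table. In all, 10148 of 16482 genes were called, 5338 higher and 4810 lower, of which 1607 and 2125 changed by at least 2-fold.

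Of 40 stem and primitive progenitor genes, 32 fell and 3 rose (35 calls adjusted over the list alone, median -1.53, camera FDR 1.85e-21). The authors' deposited table gave Meis1, a homeobox factor of stem cells, -2.40 (standard error 0.08) and Angpt1 -2.19 (standard error 0.08). Megakaryocyte genes fell in 21 and rose in 2 of 29 (23 calls adjusted over the list alone, median -1.53, camera FDR 9.3e-10). The authors' deposited table gave Nrgn -2.52 and Plek -2.79. Lymphoid priming genes fell in 16 and rose in 3 of 21 (19 calls adjusted over the list alone, median -1.34, camera FDR 8.35e-08). The terminal transferase Dntt was at -6.56 (standard error 0.30), Sox4 at -2.10 and Mef2c at -1.78 in the authors' deposited table. B cell genes fell in 10 and rose in 1 of 25 (10 calls adjusted over the list alone, median -0.58, camera FDR 0.0439). Cyclin-dependent kinase inhibitor and quiescence genes fell in 12 and rose in 4 of 21 (16 calls adjusted over the list alone, median -0.63, camera FDR 0.0187). The authors' deposited table gave Txnip -1.43 and Ccng2 -1.75.

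Erythroid and heme synthesis genes rose in 37 and fell in 1 of 40 (38 calls adjusted over the list alone, median 2.57, camera FDR 3.12e-18). The authors' deposited table gave the heme enzyme Cpox 2.60 (standard error 0.09) and the erythropoietin receptor Epor 2.72 (standard error 0.12). Neutrophil granule genes rose in 22 and fell in 4 of 33 (28 calls adjusted over the list alone, median 2.32, camera FDR 4.03e-05). The authors' deposited table gave Ms4a3 2.92, Lcn2 5.07 and Mpo 1.33. Oxidative phosphorylation genes rose in 52 of 52 (52 calls adjusted over the list alone, median 0.83, camera FDR 7.63e-20). Ribosome biogenesis genes rose in 41 of 41 (41 calls adjusted over the list alone, median 0.79, camera FDR 1.15e-20). Replication-dependent histones rose in 48 of 48 (48 calls adjusted over the list alone, median 0.52, camera FDR 1.13e-12). Histone genes are near-identical copies, so single members are uncertain. Cytosolic ribosomal proteins rose in 71 of 76 and fell in 0 (73 calls adjusted over the list alone, median 0.52, camera FDR 7.92e-11). The authors' deposited table gave Rps2 0.70 and Rps12 1.06.

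Cell cycle genes rose in 46 and fell in 8 of 61 (54 calls adjusted over the list alone, median 0.39, camera FDR 1.27e-07). The ribonucleotide reductase subunit Rrm2 was at 1.51 (standard error 0.05), Ccne1 at 2.55 (standard error 0.13) and Cdc6 at 1.23 (standard error 0.06) in the authors' deposited table. Early spliceosome components rose in 38 and fell in 0 of 44 (38 calls adjusted over the list alone, median 0.46, camera FDR 1.78e-08). The authors' deposited table gave Phf5a 1.23, Snrpb2 0.94 and Prpf31 0.86. Stress response and unfolded protein genes rose in 23 and fell in 5 of 34 (29 calls adjusted over the list alone, median 0.60, camera FDR 1.39e-06). The authors' deposited table gave Mthfd2 1.62 and the chaperone Hspa5 1.03. DNA damage response genes rose in 32 and fell in 8 of 59 (41 calls adjusted over the list alone, median 0.20, camera FDR 0.0187). Transcripts of snoRNA hosts and other decay-sensitive transcripts rose in 17 and fell in 2 of 25 (19 calls adjusted over the list alone, median 0.71, camera FDR 0.0104). Splicing regulators rose in 31 and fell in 10 of 56 (42 calls adjusted over the list alone, median 0.23, camera FDR 0.0499). Among the splicing regulators Srsf2 was at 0.63, and the kinases Clk1 and Srpk2 at -0.72 and -1.44, in the authors' deposited table.

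The lists that did not pass in LSK were p53 targets (14 higher, 10 lower of 38, 24 calls adjusted over the list alone, where the median of -0.04 and the test, upward, differ in sign), the BCL2 family and caspases (12 higher, 20 lower of 43, 33 adjusted over the list alone), interferon-stimulated genes (15 higher, 18 lower of 47, 34 adjusted over the list alone) and inflammatory cytokine genes (4 higher, 16 lower of 29, 20 adjusted over the list alone). Immediate early genes (0 higher, 8 lower of 22, 7 adjusted over the list alone) and monocyte and dendritic cell genes (10 higher, 6 lower of 37, 15 adjusted over the list alone) did not pass. The same holds for T, NK and innate lymphoid genes (5 higher, 3 lower of 33, 7 adjusted over the list alone), and mast cell, basophil and eosinophil genes (14 higher, 2 lower of 22, 16 adjusted over the list alone, camera FDR 0.0562, and 0.00749 with ranks). Endothelial and stromal genes had 6 higher and 6 lower of 24 (12 adjusted over the list alone), with a median of 1.24 that differs in sign from the test, which was downward and did not pass. The camera FDR of these lists ran from 0.0562 to 0.97.

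Among genes with a mean of at least 100, the largest falls in the authors' deposited table were the Y-linked genes Ddx3y (-9.21), Eif2s3y (-9.15), Uty (-9.06) and Kdm5d (-8.95), followed by Lhcgr (-7.15), Pgr (-7.12), Apob (-6.81), Dntt, Obsl1 (-5.79) and Scube3 (-5.59). The largest rises under the same limit in the authors' deposited table were Sparcl1 (10.89), Hpcal4 (9.60), Cpe (8.50), Slc1a2 (8.45), Xist (7.49), Map2 (6.82), Camk2n1 (6.19), Kif1a (6.17), Erdr1 (6.03) and Epx (5.74). Sparcl1, Hpcal4, Cpe, Slc1a2, Map2, Camk2n1 and Kif1a are abundant in neural tissue, and the derived WT means of Sparcl1, Hpcal4 and Cpe were below 1. Standard errors for the Y-linked genes were 0.38 to 0.46 in the authors' deposited table. The derived mean of Ddx3y was 4.99 under the label KO and 2949 under WT. Sex of the animals and genotype label therefore cannot be separated in LSK. With a preset correlation of 0.05, 12 of the 17 list calls held, without B cell, quiescence, DNA damage, snoRNA host and splicing regulator lists, and recentring also ended the calls for B cell genes (FDR 0.058) and splicing regulators (FDR 0.103).

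**Figure D1:**
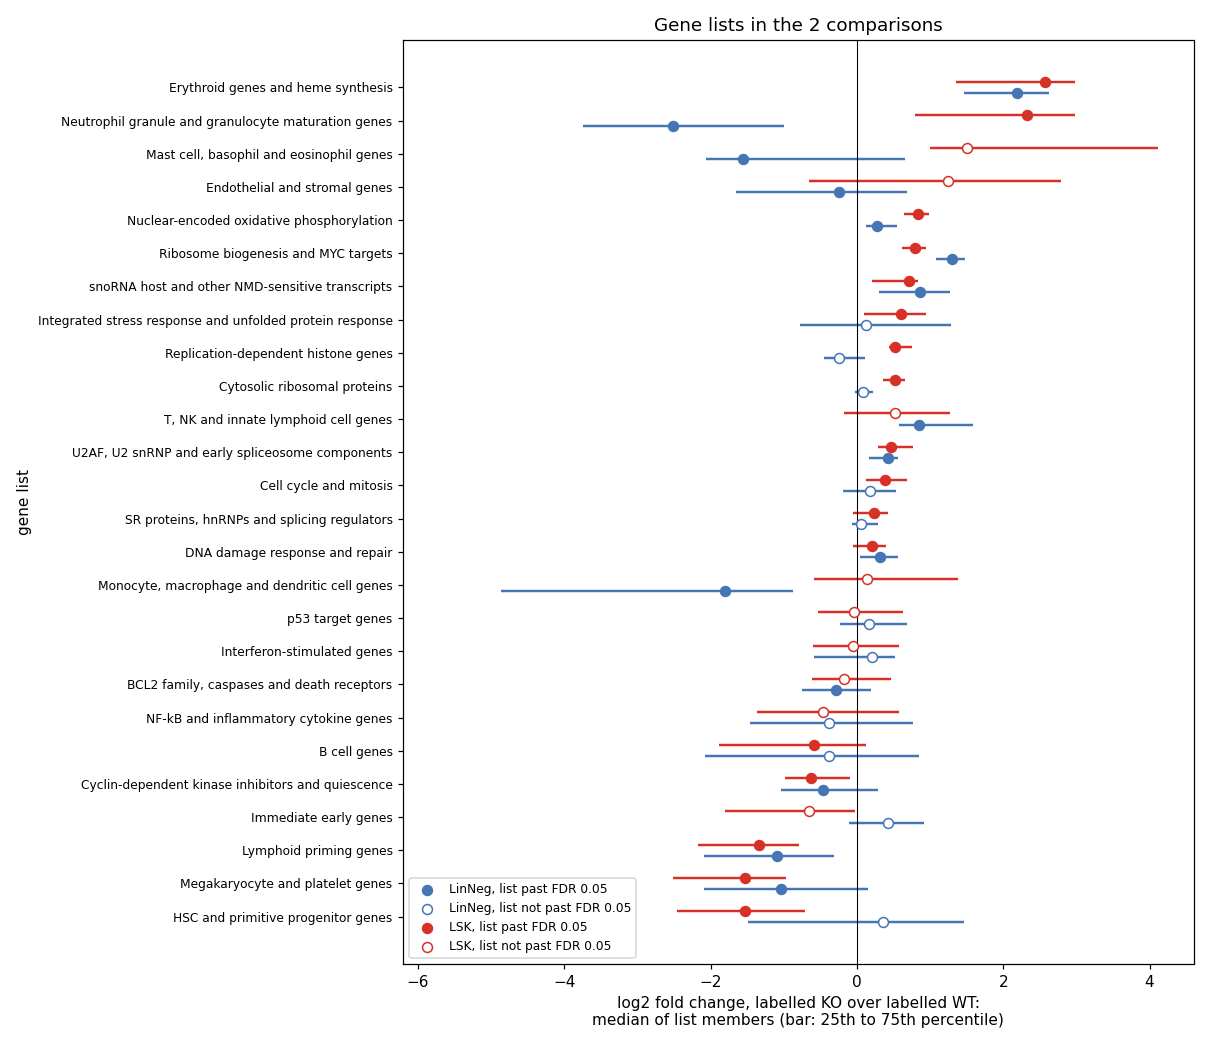
Median log2 fold change of the tested members of each gene list (x axis, libraries labelled KO over WT; bars, 25th to 75th percentile of members) in LinNeg (blue) and LSK (red), with filled points for lists past FDR 0.05. Neutrophil granule genes lie at -2.51 in LinNeg and 2.32 in LSK, and erythroid genes at 2.19 and 2.57.

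Between the populations, the effect on myeloid genes differed most and that on erythroid genes did not pass the test of a difference. Neutrophil granule genes were higher in LSK than in LinNeg relative to their WT libraries by a median of 5.18 (called differences higher in 25 and lower in 0 of 30, camera FDR 1.68e-26), and monocyte and dendritic genes by 2.32 (25 higher and 0 lower of 37, camera FDR 5.41e-27). Elane was at -2.71 in LinNeg and 2.52 in LSK in the authors' deposited tables, and F13a1 at -6.12 and 0.97. Mast cell, basophil and eosinophil genes differed by 2.90 (camera FDR 4.73e-08), histones by 0.77 (camera FDR 3.68e-08), oxidative phosphorylation by 0.46 and cytosolic ribosomal proteins by 0.39 (camera FDR 0.000221 for both). Stem and progenitor genes were lower in LSK by a median difference of -1.44 (called differences lower in 23 and higher in 5 of 40, camera FDR 8.59e-07), immediate early genes by -1.39 (camera FDR 0.0378) and ribosome biogenesis genes by -0.47 (camera FDR 0.00064). Erythroid genes had a camera FDR of 0.833 and early spliceosome components one of 0.857. The LSK group also carries the label BMT, so the difference has no single reading.

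By gene, 5025 of 15735 differences were called, 2743 higher and 2282 lower in LSK. That balance was not stable: recentring gave 3415 higher and 1995 lower, and a difference of at least 1 left 1300 higher and 1624 lower. Among genes with a mean of at least 100 in both tables the largest were Mefv (10.11), Sparcl1 (9.18), Cpe (8.03), F13a1 (7.08) and Lcn2 (7.02) on the positive side, and Myo5c (-8.91), Ddx3y (-8.42), Uty (-8.39), Eif2s3y (-8.29) and Kdm5d (-8.04) on the negative side. Myo5c was at 5.06 in LinNeg with a standard error of 1.85 in the authors' deposited table. Ddx3y, Uty, Eif2s3y and Kdm5d are Y-linked, and sex and genotype label cannot be separated in LSK. Calls overlapped in the same direction for 4134 genes: 2218 rose in both (1172 for independent lists, odds ratio 5.21, 95% interval 4.81 to 5.64) and 1916 fell in both (987 for independent lists, odds ratio 4.82, 95% interval 4.44 to 5.23). Recentring turned that balance to 1683 shared rises and 2370 shared falls. A further 968 genes were called in opposite directions, 428 higher in LinNeg and lower in LSK (Fisher's exact p = 3.67e-173 for a deficit) and 540 the reverse (Fisher's exact p = 6.44e-128), and all 968 had a called difference. Across genes, which are not independent replicates, the log2 fold changes of the tables had a Pearson r of 0.28 and a Spearman rho of 0.338, and of 0.425 and 0.515 for the 10425 genes with a mean of at least 100 in both.

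**Figure D2:**
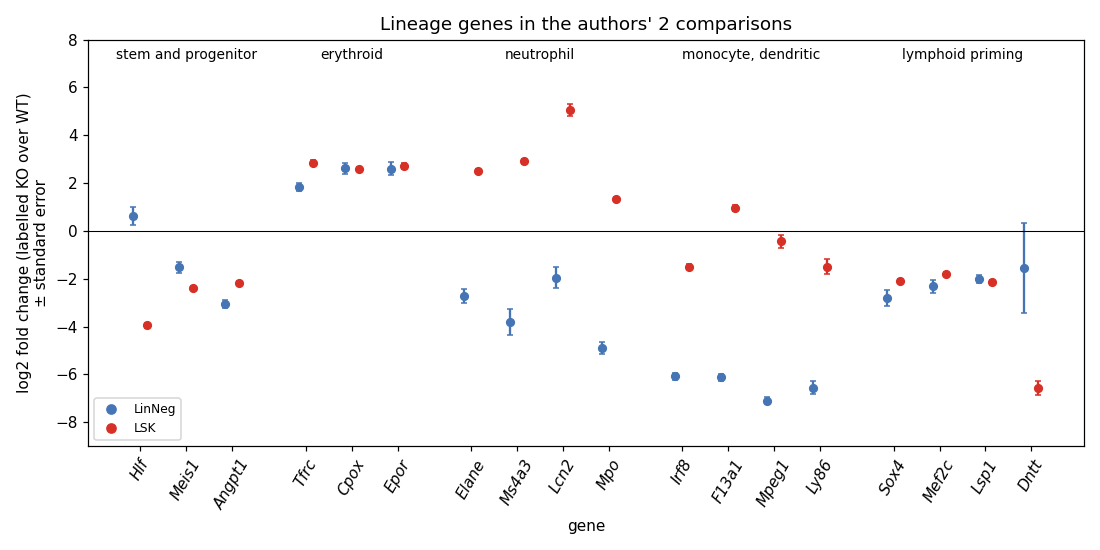
Log2 fold changes of libraries labelled KO over WT, with the authors' standard errors, for list members among the 4 with the smallest adjusted p (stem, erythroid, neutrophil and lymphoid priming genes chosen in LSK, monocyte and dendritic genes in LinNeg), in LinNeg (blue) and LSK (red). Elane stands at -2.71 in LinNeg and 2.52 in LSK, and Tfrc is above 0 in both.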

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

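The tests of other-organ transcripts, sex-linked genes and U2af1 were chosen after the results were seen, and the weight given to each is limited by that.

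Differences between the populations. The effect differed for 5025 genes, and among genes with a mean of at least 100 in both tables the largest differences were positive for Mefv (10.11), Sparcl1 (9.18), Cpe (8.03), F13a1 (7.08) and Lcn2 (7.02), and negative for Myo5c (-8.91), Ddx3y (-8.42), Uty (-8.39), Eif2s3y (-8.29) and Kdm5d (-8.04). Apart from Myo5c, whose LinNeg standard error was 1.85, the negative genes are Y-linked. By list the median differences were 5.18 for neutrophil granule genes, 2.90 for mast cell, basophil and eosinophil genes, 2.32 for monocyte and dendritic genes, 0.77 for histones, 0.46 for oxidative phosphorylation, 0.39 for cytosolic ribosomal proteins, 0.30 for stress response genes, -1.44 for stem and progenitor genes, -1.39 for immediate early genes and -0.47 for ribosome biogenesis genes. The stress response difference had a camera FDR of 0.0147, and of 0.177 with ranks. That of cell cycle genes did not pass, with a camera FDR of 0.128, but had one of 0.00937 with ranks (19 higher and 3 lower of 61 in LSK).

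U2af1 was at 0.65 in LinNeg and 0.61 in LSK in the authors' deposited tables, in a series that names its loss. Recentring on the median gene left 0.50 in LinNeg, the smaller of the pair, with an adjusted p of 0.0279 (two-sided normal test). The median gene stood at 0.16 in LinNeg and 0.04 in LSK, so recentring could take off only that much. It cannot show whether the authors' scaling was off in another way, so scaling stays open as a source. U2af1 lay at the 61.4 percentile of the early spliceosome list in LSK and the 81.8 percentile in LinNeg. Among all tested genes it lay at the 74.6 percentile in LSK and the 66.9 percentile in LinNeg. A rise shared with the other members of that list may be part of it. The percentiles cannot show this, because a gene can lie inside the list's range without sharing its rise. A fold change deposited with the sign turned, which would make the LSK ratio 0.65, cannot be told apart, because nothing in a table of fold changes forbids it. Reads over exons outside a deleted part stay open and untested.

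Sex-linked genes stood apart in LSK: Ddx3y was at -9.21 and Xist at 7.49 in the authors' deposited table, and the 5 X-linked genes that escape inactivation had a median of 0.84, where the other X-linked genes lay -0.07 from the autosomes. This pattern is consistent with more female animals among the libraries labelled KO. In the LinNeg table Xist was at 10.02 while Ddx3y was at -0.79 with a standard error of 1.64, in the authors' deposited table, so libraries of both kinds may be mixed under a single label there. Genes on X and Y make up 3.35% of LSK calls, and whether sex changes autosomal genes cannot be told apart from genotype, because the labels split the libraries alike.

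Transcripts of other organs had log2 fold changes above 2 in LinNeg in 11 of 11 seminal vesicle genes (11 called higher), 8 of 10 prostate (7 called), 14 of 17 liver (6 called), 12 of 15 testis (1 called), 7 of 11 kidney (5 called), 9 of 16 thymus (1 called), 6 of 9 intestine (0 called), 4 of 8 lung (2 called), 2 of 12 heart and muscle (1 called) and 0 of 11 pancreas genes (1 called), so many of these rises did not pass. The pancreas list went the other way, with 4 of 11 genes below -2, 1 called lower and a median of -0.89. Over the liver, kidney, testis and pancreas lists the share above 2 was 61.1%. Such a share would be seen with reads from several organs, but the pancreas genes had no part in it. Many of the genes above 2 had a derived WT mean below 1, such as Prm2 (0.341), Ttr (0.186) and Cdh16 (0.680). Their fitted folds are not measured ratios. In LinNeg, 6 thymus, 5 heart and muscle, 2 testis, 1 pancreas and 1 seminal vesicle gene have a derived WT mean of at least 100, so they were also present under the label WT. The standard errors of seminal vesicle genes were 10.52 times those of other genes at the same mean (95% bootstrap interval over the genes 10.31 to 10.79). That interval resamples genes and does not measure variation between libraries. The size of the ratio argues against a rise of that list shared evenly by all 3 libraries labelled KO. Other ratios were 4.13 for prostate, 3.44 for thymus, 1.91 for liver, 1.48 for testis, 1.20 for kidney and 1.06 for lung and intestine. They have no interval and leave this open. Apart from these ratios, 9 of 16 thymus, 6 of 15 testis, 3 of 17 liver and 2 of 10 prostate genes had no p. The seminal vesicle, kidney, lung and intestine lists had 0 such genes. DESeq2 leaves out the p when single libraries stand far out. For those genes this argues against an even rise over the 3 libraries labelled KO, although which library stood out is unknown. How such reads entered, and a biological source, stay open.

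Reads outside annotated features had a log2 fold change of -0.47 (adjusted p = 2.01e-22) in the authors' deposited table for LSK. In LinNeg the log2 fold change from DESeq2, run by the authors, was 0.01 (adjusted p = 0.972). Of the genes with a fold change and no p, 47 of 53 were higher in libraries labelled KO in LinNeg and 3 of 3 in LSK, the latter being Ccr3, Ear1 and Siglec1.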

How the results depend on the processing

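No paired analysis was possible because the tables hold no values per library. For the same reason other splits of the libraries, leaving out single libraries, limma-voom, library-size scaling, pseudocounts, an estimated correlation and fry were not run. No filter, the low mean filter and the fold change threshold within tables were chosen before the data were examined. All other alternatives, with the threshold on differences, were chosen after seeing the data. Calling only absolute log2 fold changes of at least 1 left 4043 LinNeg genes, 3732 LSK genes, 1199 genes shared in direction and 2924 differences, by construction. With log2 fold changes in the list test, 6 LinNeg and 9 LSK lists passed, and relative to the other genes the LinNeg lists for DNA damage and oxidative phosphorylation turned to -0.12 each (FDR 0.806) and early spliceosome to -0.03 (FDR 0.957). Ribosome biogenesis lost its call there in LinNeg (FDR 0.0871) and LSK (FDR 0.0715), as did LSK cell cycle (0.412), early spliceosome (0.324), and ribosomal protein, histone and stress response lists (0.189 each). With a preset correlation of 0.05, 5 LinNeg lists passed. A mean of at least 100 ended the LinNeg calls for BCL2 family (0.065), quiescence (0.0569), mast cell (0.0563) and endothelial genes (0.065), and ranks that for endothelial genes (0.202). In LSK, mast cell genes gained a call with ranks (0.00749), log2 fold changes (2.25e-06) and recentring (0.0464), immediate early genes with ranks (0.0314) and log2 fold changes (0.0466), NF-kB genes with ranks (0.0375) and endothelial genes at a mean of at least 100 (0.03). In LinNeg, histones gained one with ranks (0.0108), B cell genes with log2 fold changes (0.00377) and stem cell genes at a mean of at least 100 (0.033). For the LSK splicing regulators the FDR was 0.114 at a mean of at least 100 and 0.99 with log2 fold changes. For LSK DNA damage genes these values were 0.0582 and 0.846. LSK B cell genes lost their call at a mean of at least 100 (0.0702). Quiescence (0.647) and snoRNA host genes (0.189) lost theirs in LSK with log2 fold changes. The cause was not tested. Under the other alternatives the gene counts ran from 5448 to 7141 in LinNeg and from 8449 to 10145 in LSK, differences from 3959 to 5410 and shared calls from 3808 to 4053. Recentring left 12 LinNeg and 16 LSK lists, and moved the higher share of LinNeg calls from 53.3% to 42.4%, and U2af1 kept its direction and call, at 0.50 to 0.65 in LinNeg and 0.57 to 0.61 in LSK. All 948 values of single named genes under 4 alternatives kept direction and call. Except for recentring, these alternatives kept the fold change and p and only redid the adjustment, so the direction could not change. The genes were also named for small adjusted p or large called changes, so this outcome was largely fixed in advance. Of the single list values 202 kept their call or the lack of one, 45 lost their call in the same direction, 3 lost it with the sign reversed and 10 gained a call. Among the 202, direction was required to hold only where the list was called. Without values per library the depth behind each gene is unknown.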

Other observations

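The tests reported in this part were chosen after the tables were seen, except for those of cytosolic ribosomal proteins and of oligodendrocyte and unseen neuron genes. The cytosolic ribosomal protein list was fixed before the data were examined. The oligodendrocyte and unseen neuron genes were tested on a bound set before their values were seen.

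Aminoacyl-tRNA synthetases, chaperonins, proteasome subunits and mitochondrial ribosomal proteins were higher in libraries labelled KO in both populations, while cytosolic ribosomal proteins passed in LSK only. Of 20 aminoacyl-tRNA synthetases 20 rose in LinNeg (median 1.07) and 20 in LSK (median 0.83), and of 20 chaperonins and heat shock proteins 20 rose in LinNeg (median 0.89) and 19 in LSK (median 0.74). Hspd1, a mitochondrial chaperonin, was at 2.08 in LinNeg and 1.37 in LSK in the authors' deposited tables. Proteasome subunits rose in 21 of 31 and 31 of 31 (camera FDR 0.000234 and 1.78e-17), and mitochondrial ribosomal proteins in 27 of 34 and 34 of 34 (camera FDR 1.77e-05 and 6.42e-09). Metallothioneins and metal response genes rose in 6 of 14 and 9 of 14 (camera FDR 0.00622 and 0.000137): Mt2 was at 4.72 and 4.40 and Mt1 at 3.63 and 3.74 in the authors' deposited tables.

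MHC class II presentation genes fell in 9 of 10 in LinNeg (median -2.60, camera FDR 2.07e-09) and in 4 of 10 in LSK (median -0.16, camera FDR 0.0443), with H2-Ob at -2.63 and -2.49 in the authors' deposited tables. Lysosome and autophagy genes fell in 15 of 24 in LinNeg (camera FDR 1.3e-06), and in LSK 14 of 24 were higher and 6 lower (camera FDR 0.233). The GIMAP family fell in 6 of 8 in LSK (median -2.29, camera FDR 1.53e-05), with 4 higher and 2 lower of 8 in LinNeg (camera FDR 0.315). Glycolysis genes rose in 12 of 16 in LSK (camera FDR 0.00198) and had 5 higher and 7 lower of 16 in LinNeg (camera FDR 0.41). Cholesterol synthesis (camera FDR 0.59 in LinNeg and 0.108 in LSK) and the Hoxa and Hoxb genes (0.986 and 0.158) did not pass, and the Hox median of 0.26 in LinNeg differs in sign from its test.

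Neural transcripts were higher in LSK libraries labelled KO: 13 of 16 astrocyte, 14 of 20 neuron and 8 of 11 oligodendrocyte genes had a log2 fold change above 2, beside 7 of 16, 9 of 20 and 9 of 12 in LinNeg. Of the oligodendrocyte and unseen neuron genes 19 of 28 did so in LSK, or 67.9%. Among those above 2, only Gad1, Mag and Ugt8a had a derived WT mean of 1 or more (2.68, 2.31 and 7.41). For the rest the fitted folds are not measured ratios. The share would be seen with reads from brain tissue, but it rests mostly on genes near the floor under the label WT. Of genes named beforehand for that test, Snap25 was at 7.58 and Mbp at 0.38 in the authors' deposited table, so Mbp stayed under the bound. Mbp had a derived WT mean of 4710 and a KO mean of 6129, and at that level its small fold neither speaks for nor against brain reads. In LSK, 32 neural genes were both called and above a log2 fold change of 2. Their standard errors were 1.43 times those of other genes at the same mean (95% bootstrap interval over the genes, not the libraries, 1.29 to 1.91). This leaves open whether a single library carries them. Of these lists, 2 neuron, 3 astrocyte and 2 oligodendrocyte genes have a WT mean of at least 100 in LSK.

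In LSK, a log2 fold change above 2 was seen in 1 of 2 seminal vesicle, 0 of 1 prostate, 2 of 11 testis, 2 of 8 liver, 4 of 9 kidney and 0 of 4 pancreas genes with a fold change. It was also seen in 4 of 11 heart and muscle, 1 of 4 lung, 0 of 6 intestine and 1 of 16 thymus genes.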
